A study of Mus musculus with 12 samples.

How the data were processed

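Gene expression was measured on 12 Illumina mouse bead arrays, 3 in each of 4 groups (SQ, BE, BA and TU), in epithelium taken by laser microdissection from frozen stomach sections of 20 µm. RNA was amplified with a kit for small amounts and labelled with biotin. Groups were taken from the sample titles, with SQ as wild-type squamous epithelium, BE and BA as metaplasia and TU as adenocarcinoma of the interleukin-1β transgenic mice. The protocol gives deoxycholate, a bile acid, at 0.2% in the drinking water for 9 to 12 months. SQ and TU shared 1 chip of 6 arrays, and BE and BA the other.

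The deposited report without normalization gives, for each probe and array, a mean bead intensity, to which the authors applied neither normalization nor background subtraction, together with the standard error over beads in the same intensity unit. The detection p-value deposited beside each signal compares it with the negative control beads of the array and was computed in GenomeStudio (2010.1 per the submitters' processing notes). A second deposited report holds intensity values that the authors subtracted the background from and quantile-normalized in GenomeStudio. The deposited series matrix holds the same values as that report (0 differ). The deposited summary table gives control bead intensities and the count of genes that GenomeStudio called detected on each array. The submitters' notes also name limma, without a version, and no file holds its output. Every per-sample column of these files was used (0 left out). A further file repeats the signals without normalization and was not analysed here.

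Of 45281 probes, 29586 were named by their Entrez gene ID, 2759 by accession and 12936 kept the symbol in the file, which gave 30561 distinct names. The files left 2 report lines without values, which were left out. Signals were corrected with limma's neqc, which infers the negative controls from the detection p, adds an offset of 16, quantile-normalizes and takes log2. A probe was tested when its detection p was under 0.05 on at least 3 of the 12 arrays (15234 probes), whichever groups those arrays came from. Each gene was represented by its brightest tested probe, which left 11608 genes, 2639 of them with more than 1 tested probe.

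Depth on an array is signal over background. The negative control signal ranged from 32.6 to 115.3 between arrays, and the lowest log2 value of a detected probe from 4.59 to 5.33. Where no array on one side of a comparison detected a gene, each array's value there was raised to that lowest value and the difference recomputed, which gives a lower bound on the fold. The adjusted p printed beside a bound comes from the fit without raised values and does not test the bound. A gene detected on neither side, or so dim that the raised values exceed the detected side, has no bound and is not read as changed by itself. The counts of called genes and list members do include genes with a side not detected. Against SQ these were 1621 of 6666 called genes for the lesions and 1942 of 5940 for BE. They were 2585 of 6214 for BA and 1615 of 6133 for TU. For BA against BE they were 1063 of 3622. For TU they were 632 of 4100 against metaplasia, 728 of 3967 against BE and 1236 of 4046 against BA. With 3 arrays per group, the number of arrays limits the precision.

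All arrays were fitted together in limma (lmFit and eBayes, without trend and not robust) with a mean for each of the 4 groups, leaving 8 residual degrees of freedom and 3.58 prior degrees of freedom. There were 8 comparisons: the mean of BE, BA and TU against SQ, each of the 3 against SQ, BA against BE, TU against the mean of BE and BA, and TU against BE and against BA. P-values are two-sided from limma's moderated test, adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. SE is limma's moderated standard error. Calls shared by BE, BA and TU against SQ were counted in each direction, beside the number expected from independent calls and 1 simulation of unchanged groups that share the SQ arrays.

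There were 26 gene lists with 784 names, of which 2 had no current symbol and 14 no probe. They cover squamous, columnar, gastric mucous, parietal and chief cell, intestinal, and stem and progenitor genes, the Notch, Wnt, and hedgehog and BMP pathways, bile acid handling, inflammatory cytokines, interferon and MHC class II, T and B lymphocytes, myeloid cells, fibroblasts, smooth and skeletal muscle, endothelium, adipocytes, pancreatic acinar cells, proliferation, p53 targets, oxidative stress, endoplasmic reticulum stress and secretion, matrix remodelling and housekeeping. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. The sign of a list's median, mean or test differed in 24 of the list results. Counts adjusted over the list alone are given where they differ from those over all genes.

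Genes were named by a fixed rule. For each comparison it took the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, passing over names of gene models. From each list described it took up to 3 rising and 3 falling members with the smallest p, or, where none passed, up to 2 with the smallest p. It always took Il1b, Il6, Tff2, Muc5ac, Krt5, Krt8, Cdx2, Muc2, Lgr5, Dclk1, Cckbr, Notch1, Dll1 and Cxcr4 where measured. Genes of the first and second kinds were left out for length from the smallest change, and 1 gene for another reason.

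The fit was tested on simulated data with the same group sizes and spread of each gene. Values were drawn independently, without differences in array quality, shared deviations or a normalization step. Of genes given a log2 change of 1, between 83% and 95% were called in the 8 comparisons, and of those given 0.5 between 22% and 58%. Among 11408 unchanged genes 5 to 10 were called. A simulated list that moved passed in 8 of 8 comparisons, and 0 of 200 lists that did not move passed. Real arrays shared deviations, with a correlation of 0.67 between BE replicate 2 and BA replicate 1 after the group means were removed. Genes of a list could be correlated too, with an estimate of 0.355 for skeletal muscle. The simulated rates therefore hold for independent genes and arrays and are not read as error rates of the real data. The ratio of the variance between arrays to that of the beads was 0.95 for simulated arrays with bead noise alone.

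The alternatives tried were no background correction, the deposited quantile-normalized signals (raised to 1 where lower, then log2), cyclic loess and median scaling in place of quantile normalization, a detection p under 0.01 on 3 arrays, a detection p under 0.05 on all 12 arrays, no detection filter, the mean of a gene's probes, every probe by itself, eBayes with trend and robust, array weights, only the groups of the comparison, the chip as a block, the labels' replicate number as a block, each array left out in turn, and fry in place of camera. Other splits of the arrays into groups of the same sizes were counted in fits of the groups compared. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome came with the series, so genes are given by symbol without coordinates.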

Results

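Expression was measured in epithelium taken by laser from 20 µm frozen sections of mouse stomach, on 12 Illumina bead arrays in 4 groups of 3. The SQ arrays held normal squamous epithelium of wild-type C57/B6 mice aged 12 months. The BE, BA and TU arrays came from mice with an interleukin-1β transgene, used as a model of Barrett's esophagus, in which a columnar lining replaces squamous epithelium. BE and BA held metaplasia at 12 months, and TU held adenocarcinoma at 15 months from mice given bile acid in their water. The labels of BE and BA contradict each other. BE is labelled as given bile acid and as having intestinal metaplasia, while BA is labelled as untreated and as having metaplasia brought on by bile acid. Both groups were kept under their titles, and no difference between them is read as an effect of bile acid. The protocol's ages (15 months for the Barrett tissue, 9 months for bile acid treatment) also differ from the age labels.

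Detection differed between groups. Per the deposited summary table, the mean number of genes detected at p 0.05 was 6726 on SQ (range 6090 to 7195), 6462 on BE (4141 to 8041), 5619 on BA (4773 to 6206) and 9589 on TU (7840 to 12248). The signal of the negative control beads was 115.3 on BE replicate 2 and 112.4 on BA replicate 1, against 32.6 on TU replicate 1. SQ and TU lay on 1 chip and BE and BA on another, so TU against SQ and BA against BE were compared within a chip. BE and BA against SQ and TU against metaplasia lie across the chips, where chip and groups cannot be told apart. Of the 3 lesion groups TU alone shared the chip of SQ. All 3 differ from SQ in genotype as well as tissue, so these cannot be told apart in any comparison against SQ. TU is also older than SQ, and bile acid treatment may differ too. The labels call the arrays biological replicates but do not tie them to animals or say how many animals there were, so the p-values measure only the spread between these arrays. For bright probes the variance between arrays of a group was 1.32 to 9.82 times that of the beads, and at most 1.81 times in BA and TU. With 3 arrays per group, the number of arrays limits the precision. Values are log2 differences ± SE from limma on the log2 scale of background-corrected signal plus 16, which understates the folds of dim genes. Where no array of a side detected a gene, its values there were raised to the lowest detected value of each array, and the fold is given as a lower bound ("at least"). An adjusted p beside such a fold belongs to the difference without raised values and does not test the bound.

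The series set out to compare Barrett and cancer tissue with squamous epithelium, so the mean of BE, BA and TU was first set against SQ (9 arrays against 3). Many transcripts of a glandular stomach lining were higher in the lesions. SQ held some gastric and pancreatic enzyme transcripts too, such as Pgc at a mean log2 intensity of 11.61, Chia1 at 10.29 and Clps at 10.25 (chosen after their values were seen). Tff2, a trefoil peptide of gastric mucous cells, was higher by 5.02 ± 0.17 (adjusted p = 4.4e-10), and Ghrl, which encodes ghrelin, by 4.29 ± 0.15 (adjusted p = 6.9e-10). The pepsinogen gene Pga5 was at least 19.9-fold higher (adjusted p = 3.5e-12), Sox9, a transcription factor of progenitor cells, at least 13.9-fold (adjusted p = 3.5e-12), and the keratin of simple epithelia Krt8 at least 4.61-fold (adjusted p = 7.7e-10). Several keratins and cornified-envelope genes of squamous epithelium fell, with Krt4 at -3.38 ± 0.25 (adjusted p = 3.1e-07), Sprr3 at -2.79 ± 0.11 (adjusted p = 1.7e-09) and the basal keratin Krt5 at -1.60 ± 0.10 (adjusted p = 3.9e-08). Other keratins, given further below, rose. In all, 6666 of 11608 genes changed, 3506 higher and 3160 lower, of which 862 rose and 1045 fell at least 2-fold. Of these calls 1621 were of genes that at least 1 side did not detect. The groups did not overlap for 35.3% of genes, where chance gives 0.91%, and 348 genes had another probe called in the opposite direction.

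Of the gene lists fixed before the data were examined, the parietal and chief cell, gastric mucous and columnar ones had the highest medians. In the gastric mucous list 15 of 21 measured genes rose and 6 did not pass (median 1.90, or 1.59 with undetected genes at their bounds, adjusted p = 1.6e-07). They included the gastrokine Gkn3 (at least 14.2-fold), Mucl3 (at least 12.5-fold) and Anxa10 (3.65 ± 0.07). Of 20 parietal and chief cell genes, a list that also holds gastric endocrine genes, 18 rose and 1 fell (median 2.05, or 3.19 with the deposited quantile-normalized signals, which carry no offset, adjusted p = 4.9e-09). Hdc, which makes histamine, was higher by 3.04 ± 0.08, the somatostatin gene Sst at least 4.24-fold, and Vegfb was the member that fell (-1.83 ± 0.09). Among 25 columnar genes 20 rose and 5 did not pass (median 1.12, or 3.71 with those signals, adjusted p = 1.0e-07), with the tetraspanin gene Tspan8 at least 7.47-fold, the claudin gene Cldn2 at least 7.20-fold and the membrane mucin gene Muc1 at least 5.47-fold higher. Of 35 intestinal genes on the array 15 were measured, with 9 higher and 6 not past the test (median 0.38, or 0.25 at the bounds and 1.55 with those signals, adjusted p = 9.2e-03, or adjusted p = 6.3e-02 with an estimated correlation). Clca1, a product of intestinal goblet cells, rose by 2.26 ± 0.09, the apolipoprotein gene Apoa1 by 2.79 ± 0.09 and the antimicrobial lectin gene Reg3g at least 1.44-fold. The intestinal regulator Cdx2 and the goblet mucin Muc2 were detected on 0 arrays and were not tested. Muc5ac, the mucin of gastric surface cells, differed by 0.30 ± 0.23 (adjusted p = 2.9e-01), or by 0.42 without BE replicate 2 (adjusted p = 1.8e-02).

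Squamous genes fell as a list, with 29 of 41 lower, 7 higher and 5 not past the test (median -1.06, adjusted p = 6.4e-06). Besides Krt4, Sprr3 and Krt5, Lgals7 (-1.86 ± 0.07) and the filaggrin gene Flg (-1.98 ± 0.08) fell. The members that rose included the keratins of activated or wounded epithelium Krt17 (2.18 ± 0.11), Krt16 (at least 2.52-fold) and Krt6a (at least 2.01-fold). All 14 smooth muscle genes were lower (median -2.02, adjusted p = 2.3e-10), such as Actg2 at -3.14 ± 0.10, Myl9 at -3.03 ± 0.08 and the desmin gene Des at -2.40 ± 0.09. Of 10 skeletal muscle genes 8 fell (median -1.01, or -0.82 at the bounds and -2.32 with the deposited quantile-normalized signals, adjusted p = 2.5e-03, or adjusted p = 2.4e-01 with an estimated correlation), among them the skeletal actin gene Acta1 (at least 4.38-fold lower) and Tcap (-1.52 ± 0.10). On SQ replicate 1 the 9 skeletal muscle genes outside the smooth muscle list were higher by 0.89 than on the other SQ arrays. Of 22 fibroblast genes 11 fell and 3 rose (median -0.30, adjusted p = 3.4e-02, or adjusted p = 1.2e-01 with an estimated correlation), and with median scaling their median turned to 0.10. The deposited quantile-normalized signals gave a median of -0.52. The matrix genes Postn (-1.29 ± 0.10) and Lum (-1.20 ± 0.10) were among those that fell. The largest falls of single genes further included Dnajc6 (-3.68 ± 0.23), of which 1 other probe was called in the opposite direction, Pdlim3 (-3.48 ± 0.14), Nol4l (-3.44 ± 0.26), Pgm5 (-3.24 ± 0.15) and Alox5ap, which serves leukotriene synthesis (-3.24 ± 0.29).

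Genes of protein secretion rose with the glandular genes. Of 25 genes for endoplasmic reticulum stress and secretion 18 rose and 1 fell (median 0.89, adjusted p = 1.3e-05), with Ern2, a stress sensor of mucus-secreting epithelium, at 2.02 ± 0.07, the translocon gene Ssr4 at 1.85 ± 0.07 and the stress-induced factor Ddit3 lower at -1.45 ± 0.10. All 9 pancreatic acinar genes rose (median 0.92, or 2.37 with the deposited quantile-normalized signals, adjusted p = 5.0e-04), including the elastase gene Cela1 (at least 2.76-fold) and the lipase-related gene Pnliprp1 (1.83 ± 0.13). In BE alone against SQ only 3 of the 9 rose and 6 did not pass (median 0.04, adjusted p = 2.8e-01). Of 18 stem and progenitor genes 10 rose and 1 fell (median 0.36, or 0.23 at the bounds and 1.02 with those signals, adjusted p = 3.3e-03), with Slc12a2 at 1.93 ± 0.09 beside Sox9, while Dclk1, a tuft cell gene, differed by 0.09 ± 0.10 (adjusted p = 4.7e-01). Of 38 oxidative stress genes 22 rose and 6 fell (median 0.41, adjusted p = 1.4e-02, or adjusted p = 1.8e-01 with an estimated correlation). The glutathione transferase gene Gsta1 rose by 3.78 ± 0.16, and Aldh3a1 fell (-1.97 ± 0.18).

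The remaining lists did not pass as lists in this comparison. Il1b was detected on TU arrays alone, too dimly for a bound, and the lowest detected value there was below that of most other arrays. Il6 was detected on 1 array and not tested. Inflammatory cytokine genes went both ways, 12 of 29 higher and 6 lower (adjusted p = 2.5e-01), with Cxcl16 at least 2.39-fold higher, S100a9 at least 3.37-fold higher and the decoy receptor gene Il1r2 lower at -2.09 ± 0.15. The chemokine receptor gene Cxcr4 was at least 1.09-fold higher (adjusted p = 4.4e-03 for the difference without raised values). Of 28 proliferation genes 12 rose and 2 fell (adjusted p = 1.4e-01), with Mki67 at 2.19 ± 0.10 and Plk1 at 1.82 ± 0.10. Of 15 Notch pathway genes 3 rose and 3 fell (adjusted p = 8.8e-01), such as the ligand gene Jag2 at -1.42 ± 0.09, and Notch1 and Dll1 were each detected on 1 array and not tested. The Wnt target list had 8 of 13 higher and 2 lower (adjusted p = 1.5e-01), the Wnt-dependent stem cell gene Lgr5 was detected on 1 array and the gastrin receptor gene Cckbr on 0, and neither was tested. For hedgehog and BMP genes 9 of 19 rose and 3 fell (adjusted p = 3.8e-01), with Shh at least 2.43-fold higher. Matrix remodelling genes had 8 of 16 higher and 4 lower (adjusted p = 4.2e-01), with the osteopontin gene Spp1 at least 1.85-fold higher. Myeloid genes had 8 of 20 higher and 5 lower (adjusted p = 5.4e-01), with the lactoferrin gene Ltf at least 6.46-fold higher. For the other lists the members higher and lower were 5 and 4 of 20 interferon and MHC class II genes (adjusted p = 8.8e-01), 3 and 2 of 12 lymphocyte genes (adjusted p = 6.3e-01), 1 and 2 of 7 endothelial genes (adjusted p = 5.1e-01), 2 and 0 of 6 adipocyte genes (adjusted p = 3.8e-01), 6 and 4 of 21 p53 targets (adjusted p = 8.8e-01), 2 and 1 of 9 bile acid handling genes (adjusted p = 8.8e-01) and 6 and 4 of 19 housekeeping genes (adjusted p = 9.6e-01). For the Notch list the median was 0.06 while the mean was -0.03 and the test pointed down. Adjusted over the list alone, the counts in the lesion comparison were the same for every list except oxidative stress (23 higher) and matrix remodelling (9 higher).

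**Figure D1:**
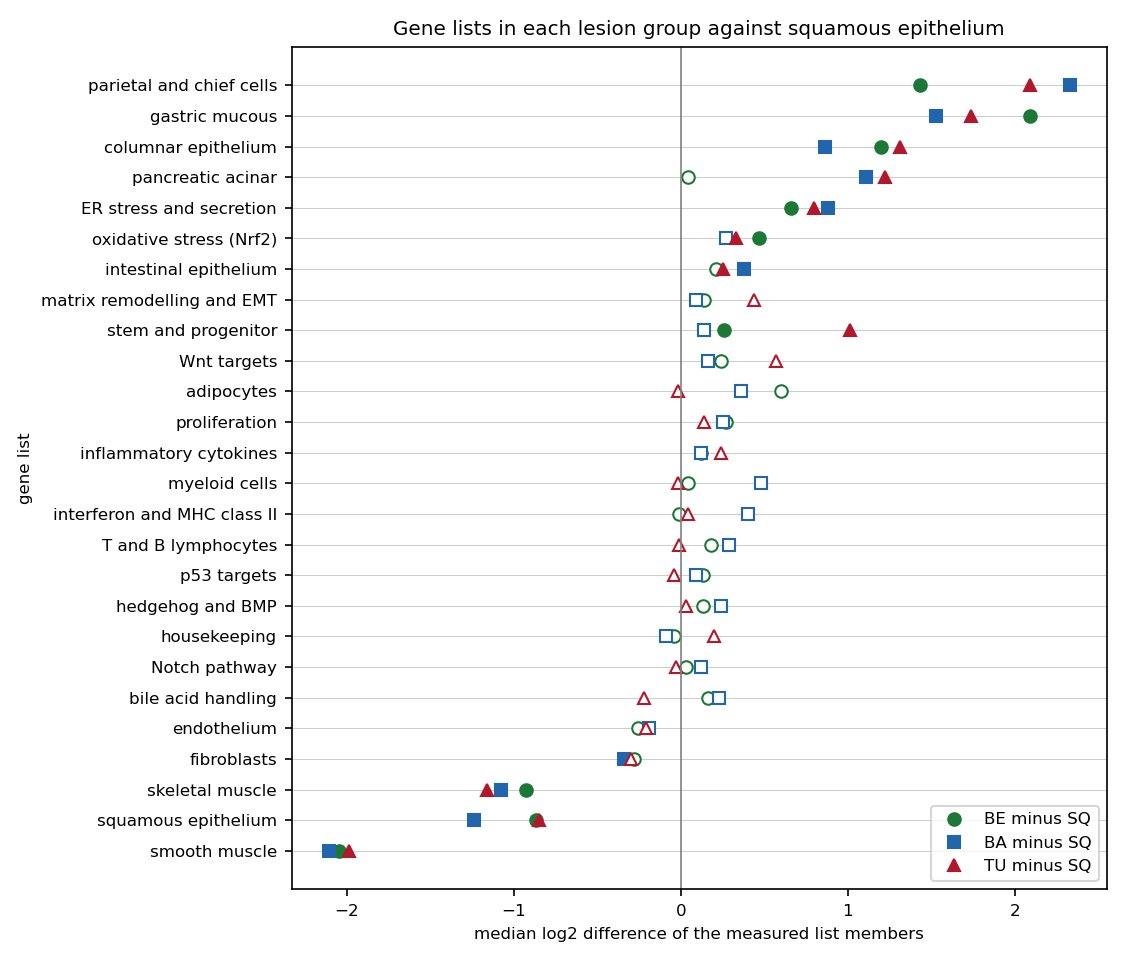
Median log2 difference of the measured members of each of the 26 gene lists (vertical axis) in BE, BA and TU against SQ (horizontal axis). Filled marks passed the camera test at adjusted p 0.05 with the preset correlation, and open marks did not. The smooth muscle and squamous lists lie below 0 and the gastric lists above 0 in each of the 3 groups.

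Each lesion group was also set against SQ by itself, 3 arrays against 3. In BE 5940 genes changed (2901 higher, 3039 lower), in BA 6214 (3120 higher, 3094 lower) and in TU, within a chip, 6133 (3285 higher, 2848 lower). The groups did not overlap for 52.9%, 64.8% and 65.6% of genes, where chance gives 10%. The same 1587 genes rose in all 3 groups and the same 2000 fell, against 221 and 199 expected if the calls were independent. Since the 3 comparisons share the SQ arrays, 1 simulation of unchanged groups against them was run. It gives almost no calls, so it does not show how much the shared arrays add to these counts. Across genes, which are not independent replicates, the fold changes correlated with r = 0.82 for BE and BA, 0.81 for BE and TU and 0.82 for BA and TU, where the simulated groups gave 0.49, 0.48 and 0.51. The covariances were 0.575, 0.513 and 0.566, against 0.014 in the simulation for each pair. Tff2 rose in each, by 4.98 ± 0.21 in BE, 4.54 ± 0.21 in BA and 5.54 ± 0.21 in TU.

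Against SQ, the largest rises in BE lay among mucous genes, Sox9 and the goblet cell gene Clca1. Clca1 rose by 4.40 ± 0.11 (adjusted p = 1.0e-10), Mucl3 at least 17.9-fold, Sox9 at least 19.4-fold and Muc5ac by 1.22 ± 0.28 (adjusted p = 2.9e-03). Gastric mucous genes had 16 of 21 higher and 1 lower (adjusted p = 1.8e-07), columnar genes 19 of 25 higher and 1 lower (adjusted p = 2.9e-08) and oxidative stress genes 22 of 38 higher and 5 lower (adjusted p = 2.5e-03, or adjusted p = 1.3e-01 with an estimated correlation). Squamous genes had 25 of 41 lower and 6 higher (adjusted p = 1.7e-04), with Krt1 at -2.83 ± 0.13, Krt4 at -3.41 ± 0.31 and Krt5 at -1.94 ± 0.12. The smooth muscle myosin gene Myh11 fell (-3.53 ± 0.13), as did the hemoglobin gene Hbb-b1 (-3.45 ± 0.10). Krt8 was at least 5.97-fold higher, Il1b was detected on neither side, and Dclk1, detected on 0 BE arrays, did not pass (-0.19 ± 0.12, but past the test at -0.31 without BE replicate 2). Adjusted over the list alone the counts were 16 and 1 for gastric mucous, 19 and 1 for columnar, 25 and 6 for oxidative stress and 7 and 26 for squamous genes, higher and lower.

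In BA the gastric, secretory and pancreatic enzyme lists rose against SQ, and so did the B-lymphocyte gene Pou2af1. This transcriptional coactivator of B lymphocytes rose by 4.06 ± 0.11 (adjusted p = 1.6e-10), Sst at least 9.19-fold and Pnliprp1 by 3.27 ± 0.16. Parietal and chief cell genes had 17 of 20 higher and 1 lower (adjusted p = 1.2e-09), pancreatic acinar genes 9 of 9 higher (adjusted p = 2.3e-04) and squamous genes 29 of 41 lower and 6 higher (adjusted p = 7.9e-07), and those counts were the same adjusted over the list alone. H2-Ab1, which encodes an MHC class II chain, rose by 1.53 ± 0.10 and Dclk1 by 0.49 ± 0.12 (adjusted p = 4.6e-03). Krt8 was at least 4.07-fold higher and Krt5 lower (-2.01 ± 0.12), while Muc5ac (-0.23 ± 0.28) did not pass and Il1b was detected on neither side. The adenosine deaminase gene Ada was at least 9.09-fold lower and Ptprs fell (-3.74 ± 0.22).

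In TU the gastric lists rose against SQ on the same chip, together with the neutrophil gene S100a9 and the acute phase gene Saa3. Genotype and age differ here along with the tissue. Gkn3 was at least 31.4-fold higher (adjusted p = 1.1e-11), Pga5 at least 25.9-fold, Cldn2 at least 17.5-fold and the simple keratin Krt18 rose by 3.87 ± 0.11. S100a9, which encodes a calprotectin subunit, was at least 8.34-fold higher and Saa3 at least 3.02-fold. Il1b was detected on 3 TU and 0 SQ arrays, too dimly for a bound on its difference, and Cxcr4 was at least 1.5-fold higher (adjusted p = 4.5e-04). Stem and progenitor genes had 11 of 18 higher and 0 lower, 12 and 0 adjusted over the list alone (median 1.01, or 0.58 at the bounds and 1.59 with the deposited quantile-normalized signals, adjusted p = 1.6e-04). Squamous genes had 28 of 41 lower and 7 higher, the same adjusted over the list alone (median -0.85, or -0.07 with median scaling, adjusted p = 1.2e-04), with Lgals7 at -2.66 ± 0.08 and Krt5 at -0.85 ± 0.12, which median scaling brought to -0.07 (adjusted p = 8.8e-01). Muc5ac (-0.10 ± 0.28) and Dclk1 (-0.03 ± 0.12, but past the test at 0.29 with median scaling) did not pass. With median scaling the median of all genes in this comparison moved by 0.42, and 86.5% of the called genes were higher in place of 53.6%.

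BA was compared with BE, the other metaplasia, within a chip (3 arrays against 3). BA had more transcript of the B-lymphocyte genes Pou2af1 and Tnfrsf13c and of the endocrine genes Chga and Sst, and less of the mucus genes Clca1 and Muc5ac. Pou2af1 was higher by 3.37 ± 0.11 (adjusted p = 6.8e-09) and Tnfrsf13c, the receptor for the B-cell survival factor BAFF, by 3.00 ± 0.09 (adjusted p = 6.6e-09). Chga, the chromogranin of endocrine cells, was higher by 2.95 ± 0.13 (adjusted p = 3.8e-08) and Sst by 1.99 ± 0.10 (adjusted p = 6.6e-08). Clca1 was lower (-2.72 ± 0.11, adjusted p = 1.8e-08), and Muc5ac was at least 1.81-fold lower (adjusted p = 1.8e-03). In all, 3622 genes changed, 1829 higher and 1793 lower, with 351 and 366 at least 2-fold, and 38.9% of genes had groups without overlap, where chance gives 10%. Without BE replicate 2 the count was 5620. With median scaling it was 2022 and with cyclic loess 3895. The share of called genes that were higher, 50.5%, became 59.1% with median scaling and 40.7% with cyclic loess.

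Of the immune lists, the interferon and MHC class II list and the myeloid list passed between BA and BE. Of 20 interferon and MHC class II genes 6 rose and 1 fell (median 0.29, adjusted p = 1.9e-02, or adjusted p = 1.3e-01 with an estimated correlation), with H2-Ab1 at 1.5 ± 0.1, B2m at 1.13 ± 0.11 and Oasl2 at least 4.52-fold higher. Of 20 myeloid genes 7 rose and 1 fell (median 0.28, adjusted p = 4.1e-02, or adjusted p = 4.6e-01 with an estimated correlation), among them the lysozyme gene Lyz2 (1.24 ± 0.11) and the leukocyte genes Ptprc (1.59 ± 0.19) and Laptm5 (1.13 ± 0.10). The lymphocyte list had 3 of 12 higher and 0 lower (adjusted p = 5.6e-01), of which Pou2af1 was the largest. The immunoglobulin genes Igk-C (2.50 ± 0.14) and Igh-VJ558 (1.75 ± 0.12), chosen after their values were seen, were higher in BA too. Of 20 parietal and chief cell genes 11 rose and 4 fell (median 0.51, adjusted p = 1.0e-03, or adjusted p = 5.3e-02 with an estimated correlation), with the chitinase gene Chia1 at 2.36 ± 0.08 besides Chga and Sst. Of 9 pancreatic acinar genes 7 rose and 2 fell (median 1.17, or 0.70 at the bounds, adjusted p = 1.0e-02, or adjusted p = 1.3e-01 with an estimated correlation), such as Pnliprp1 (2.07 ± 0.16), the colipase gene Clps (1.56 ± 0.15) and, lower, Cela1 (-1.23 ± 0.12). With the deposited quantile-normalized signals the medians were 0.50 for the interferon and MHC class II, 0.83 for the myeloid, 1.17 for the parietal and chief cell and 2.23 for the pancreatic acinar list.

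Columnar genes were lower in BA than in BE in 11 of 25 and higher in 0 (median -0.30, adjusted p = 1.7e-02, or adjusted p = 1.3e-01 with an estimated correlation), with Tspan8 at -1.12 ± 0.09, Cldn2 at -0.98 ± 0.09 and Krt8, named by itself, at -0.55 ± 0.11 (-0.49 with adjusted p = 1.8e-01 with median scaling). Squamous genes were lower in 16 of 41 and higher in 4 (median -0.22, adjusted p = 1.3e-02, or adjusted p = 1.3e-01 with an estimated correlation), led by Lgals7 (-1.86 ± 0.08) and Krt10 (-1.48 ± 0.12), while Krt16 (1.27 ± 0.13) rose and Krt5 differed by -0.07 ± 0.12 (adjusted p = 7.1e-01). Of 13 Wnt targets 7 fell and 2 rose (median -0.32, adjusted p = 4.5e-02, or adjusted p = 1.9e-01 with an estimated correlation), with the cyclin gene Ccnd1 at -1.37 ± 0.11, Sox9 at -0.81 ± 0.08 and Cd44 at -1.15 ± 0.08, of which 2 other probes were called in the opposite direction and which did not pass as the mean of its probes (-0.13). Of 21 gastric mucous genes 6 fell and 3 rose (adjusted p = 1.5e-01), with Gkn3 at -1.37 ± 0.09 and the progastricsin gene Pgc at 1.00 ± 0.12. Of 9 bile acid handling genes 1 rose and 1 fell (adjusted p = 7.3e-01), the falling one being the bile salt exporter gene Abcc3 (-1.45 ± 0.14). Further large single differences were Gdf9 (at least 9.31-fold higher), Hmga1 (2.52 ± 0.09), Stk33 (-2.78 ± 0.10), Stim1 (-2.63 ± 0.16), Cdk2 (-2.52 ± 0.09) and Ptprs (-2.49 ± 0.22). The other Cdk2 probe, the one tested when all 12 arrays had to detect a probe, gave 0.21. Dclk1 was at least 1.35-fold higher, Il1b was detected on neither side, and Tff2 (-0.44 ± 0.21, but past the test at -0.58 with cyclic loess and -0.35 with array weights) and Cxcr4 (0.47 ± 0.19, but past the test at 0.72 without BA replicate 1) did not pass. Adjusted over the list alone, the higher and lower members in BA against BE were 4 and 17 squamous, 1 and 11 columnar, 12 and 4 parietal and chief cell and 3 and 7 gastric mucous genes, and the other counts given in the text on BA against BE up to here were the same.

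**Figure D2:**
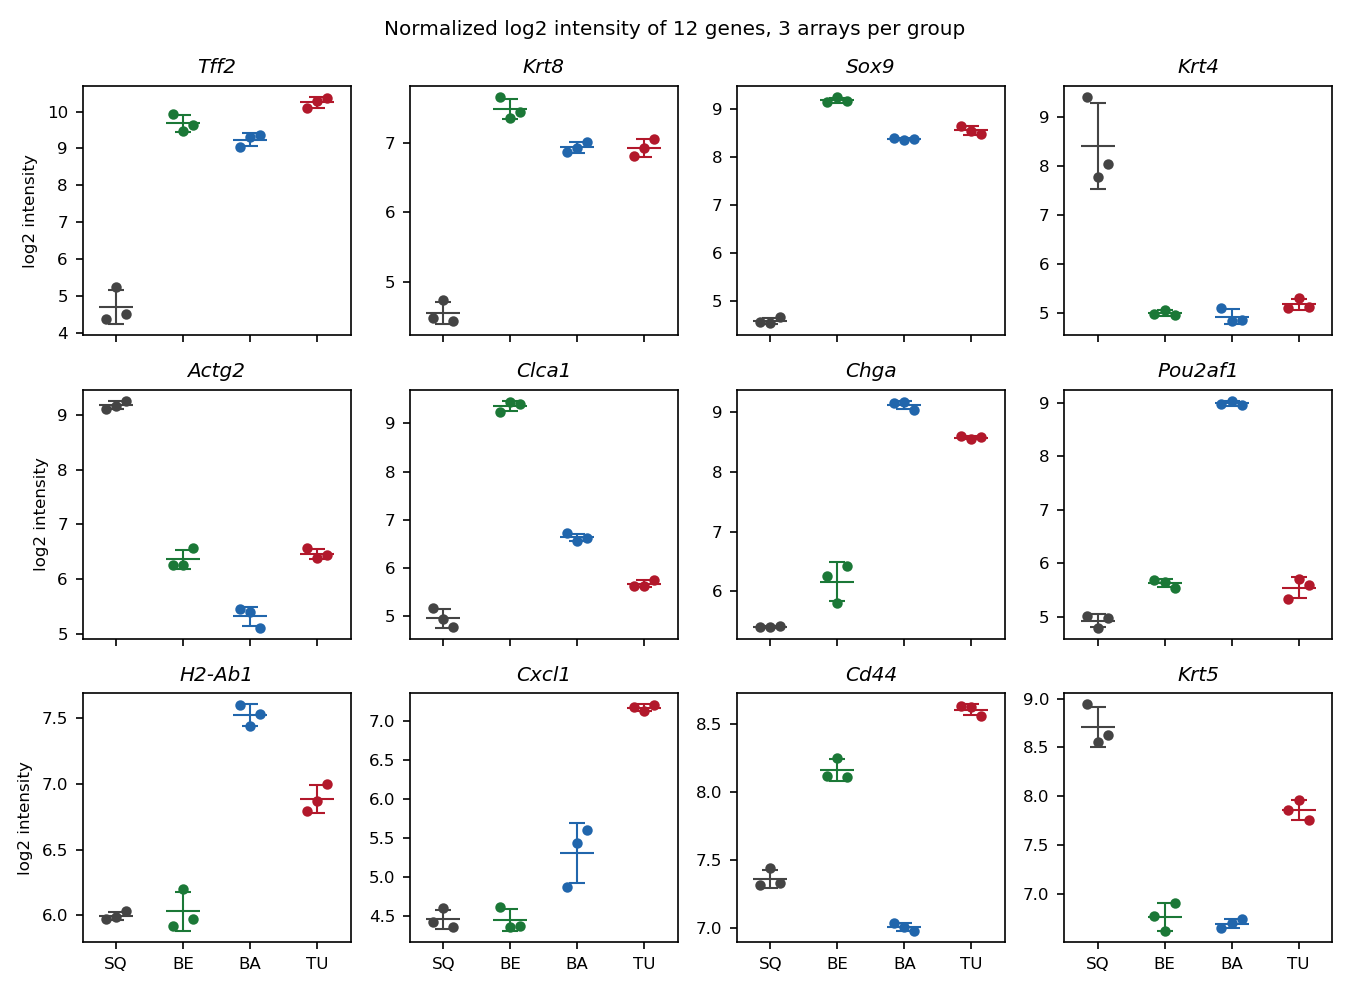
Normalized log2 intensity (vertical axis) of 12 genes on each array, by group (horizontal axis). Points are arrays, the long bar is the mean of 3 arrays and the error bar their SD. Clca1 is highest in BE, Pou2af1, H2-Ab1 and Chga in BA, and Cxcl1 in TU.

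Cancer was compared with metaplasia by setting TU against the mean of BE and BA (3 arrays against 6). TU had more transcript of Cxcl1, Cd177, S100a9 and the acute phase gene Saa3, and less of the goblet cell gene Clca1 and of Krt20. Cxcl1, a neutrophil chemokine, was higher by 2.30 ± 0.14 (adjusted p = 7.5e-07), the neutrophil surface gene Cd177 by 2.30 ± 0.11 (adjusted p = 9.4e-08), Saa3 by 2.04 ± 0.09 (adjusted p = 9.4e-08) and S100a9 by 1.96 ± 0.11 (adjusted p = 6.0e-07). Serpinb12 was at least 4.90-fold higher (adjusted p = 1.3e-08) and the secreted phospholipase gene Pla2g2a at least 4.45-fold (adjusted p = 2.7e-08). Clca1 was lower (-2.33 ± 0.10, adjusted p = 5.1e-08), as was Krt20, a keratin of surface cells (-2.06 ± 0.13, adjusted p = 7.8e-07). In all, 4100 genes changed, 2323 higher and 1777 lower, with 216 and 93 at least 2-fold, and 26.4% of genes had groups without overlap, where chance gives 2.38%. Without TU replicate 1 the count was 2587. TU also differs from BE and BA in chip and in age. Its mice were given bile acid, and BA is labelled as untreated (though its labels contradict each other), so treatment may differ too. With median scaling the median of all genes moved by 0.39 and 94.3% of the called genes were higher, so the direction of small changes rests on the scaling.

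Stem and progenitor genes had 8 of 18 higher and 1 lower in TU than in metaplasia (median 0.37, adjusted p = 3.4e-02, or adjusted p = 2.1e-01 with an estimated correlation). The adhesion receptor gene Cd44 rose by 1.02 ± 0.07, Lrig1 by 1.17 ± 0.14 and Msi1 at least 1.48-fold, while Sox9 was lower (-0.23 ± 0.07, but 0.28 with median scaling and 0.01 as the mean of its probes) and Dclk1 differed by -0.19 ± 0.11 (adjusted p = 1.8e-01, or 4.1e-02 without BE replicate 3). The call of Sox9 was also lost without BA replicate 1 (-0.22), BA replicate 3 (-0.23), TU replicate 2 (-0.22) or TU replicate 3 (-0.19). Matrix remodelling genes had 7 of 16 higher and 0 lower (median 0.29, adjusted p = 3.4e-02, or adjusted p = 2.1e-01 with an estimated correlation), including the metalloproteinase gene Mmp10 (0.99 ± 0.12), Ccn2 (0.79 ± 0.11) and Spp1 (0.58 ± 0.07). Bile acid handling genes had 3 of 9 lower and 0 higher, 4 and 0 adjusted over the list alone (median -0.30, adjusted p = 4.2e-02, or adjusted p = 2.9e-01 with an estimated correlation). They were Ugt1a6a (-0.72 ± 0.14), of which 1 other probe was called in the opposite direction and which did not pass as the mean of its probes (-0.05), Cyp3a13 (-0.64 ± 0.16) and Abcc3 (-0.53 ± 0.12). With median scaling these were -0.03, -0.03 and -0.08 and did not pass, and without TU replicate 2 Cyp3a13 did not pass either (-0.54). The medians with the deposited quantile-normalized signals were 0.88 for the stem and progenitor, 0.61 for the matrix remodelling and -0.80 for the bile acid list. Against BE by itself none of these lists passed, and against BA by itself the bile acid list did not, as given below.

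Squamous genes went both ways, 13 of 41 higher and 7 lower, or 14 and 8 adjusted over the list alone (adjusted p = 3.1e-01). The loricrin gene Lor rose by 1.63 ± 0.10, Krt10 by 1.21 ± 0.10 and Krt5 by 1.13 ± 0.10, while Lgals7 (-1.20 ± 0.07) and Krt17 (-0.91 ± 0.11, not past the test at -0.23 with median scaling) fell. Cytokine genes had 10 of 29 higher and 5 lower, 10 and 8 adjusted over the list alone (adjusted p = 4.3e-01), with a median of -0.02 (0.23 with median scaling, 0.19 with the deposited quantile-normalized signals), a mean of 0.21 and a test that pointed up. Cxcl1, Saa3 and S100a9 rose, as given, and the epithelial cytokine gene Il18 fell (-0.85 ± 0.08), while Il1b was detected on 3 TU and 0 BE or BA arrays, too dimly for a bound. Of 20 myeloid genes 3 rose and 7 fell, 3 and 9 adjusted over the list alone (median -0.36, or 0.08 with median scaling, adjusted p = 2.2e-01). Among columnar genes 9 of 25 rose and 4 fell (adjusted p = 3.9e-01), with Cldn2 at 1.92 ± 0.08 and, named by itself, Krt8 at -0.29 ± 0.10 (adjusted p = 4.1e-02, but 0.38 with median scaling), a call that was lost without BE replicate 1 (-0.25), BE replicate 3 (-0.30), BA replicate 2 (-0.29), BA replicate 3 (-0.27), TU replicate 1 (-0.23) or TU replicate 2 (-0.29). Among gastric mucous genes 5 of 21 rose and 7 fell (median -0.25, or 0.22 with median scaling, adjusted p = 5.3e-01), with Gkn3 at 1.71 ± 0.08, the water channel gene Aqp5 at 1.62 ± 0.11 and Anxa10 at -0.71 ± 0.08 (not past the test at -0.16 with median scaling). Adjusted over the list alone these counts were 10 and 6 for columnar and 6 and 10 for gastric mucous genes. Tff2 rose by 0.79 ± 0.18 and Cxcr4 by 0.68 ± 0.16, and Muc5ac differed by -0.60 ± 0.24 (adjusted p = 7.2e-02), or by -0.79 without BE replicate 2 (adjusted p = 1.4e-03). Of 28 proliferation genes 4 rose and 3 fell, 2 and 2 adjusted over the list alone (adjusted p = 7.0e-01), and Mki67 was lower in TU (-0.87 ± 0.11, but not past the test at -0.28 with median scaling). Shh, the hedgehog ligand gene, was lower too (-1.39 ± 0.09). The amylase gene Amy1 (2.36 ± 0.14) and Wfdc18 (2.34 ± 0.21) were among the largest rises, and Rep15 (-1.96 ± 0.07), Lypd8 (-1.80 ± 0.08), Plekha6 (-1.76 ± 0.11) and Ifi27l2b (-1.69 ± 0.08) among the largest falls.

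**Figure D3:**
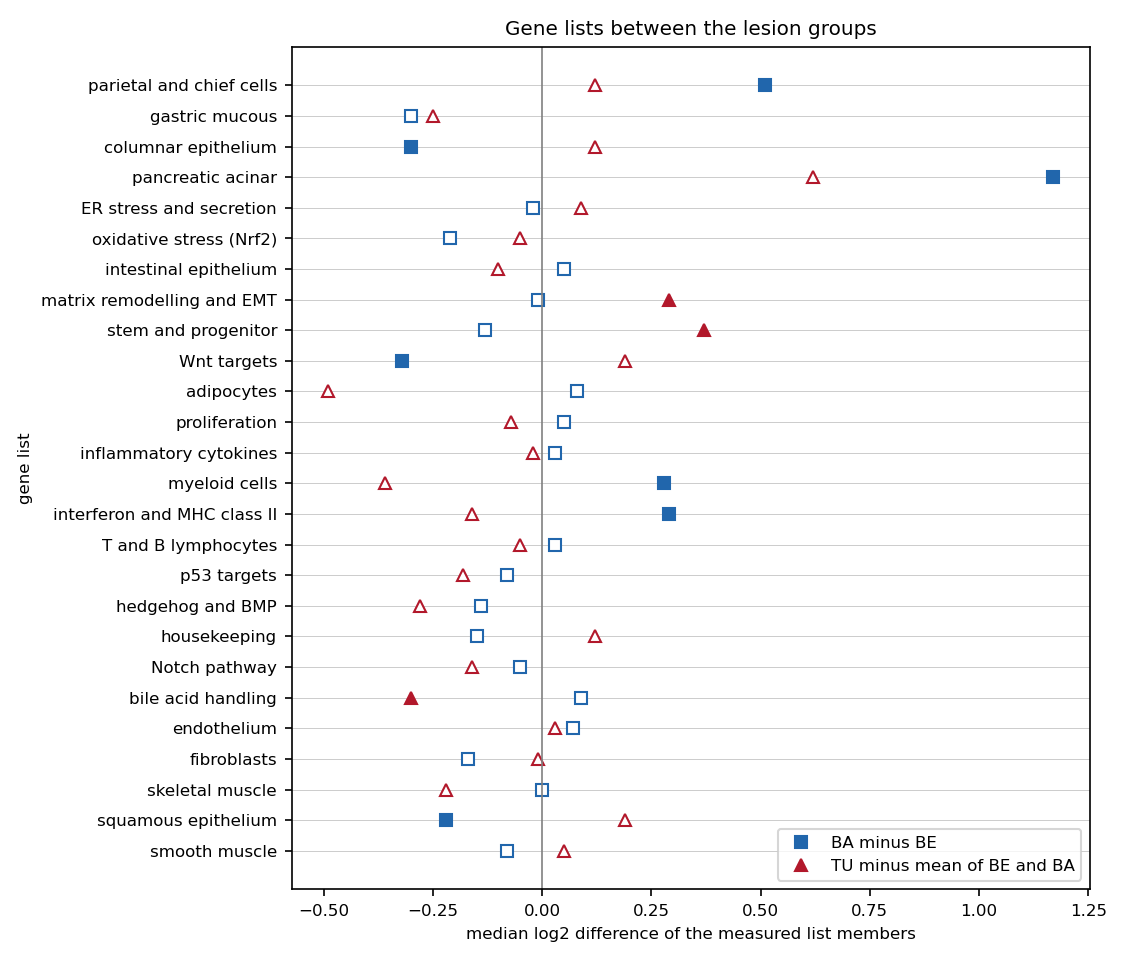
Median log2 difference of the measured members of each of the 26 gene lists (vertical axis) in BA against BE and in TU against the mean of BE and BA (horizontal axis). Filled marks passed the camera test at adjusted p 0.05 with the preset correlation, which 7 lists did in BA against BE and 3 in TU against metaplasia, and 0 lists passed in either with an estimated correlation.

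TU was also set against each metaplasia by itself. Against BE, 3967 genes changed (2311 higher, 1656 lower, 333 and 269 at least 2-fold), and 47.3% of genes had groups without overlap, where chance gives 10%. The largest falls included Clca1 at -3.69 ± 0.11 (adjusted p = 5.8e-09), Krt20 at -2.33 ± 0.15, Rep15 at -2.55 ± 0.08 and the aldo-keto reductase gene Akr1b10 at -2.81 ± 0.15, and Muc5ac fell too (-1.33 ± 0.28, adjusted p = 3.2e-03). Cd177 was at least 6.74-fold higher, Cxcl1 at least 4.58-fold and Igfbp5 rose by 2.69 ± 0.12 (adjusted p = 5.2e-08). Parietal and chief cell genes had 13 of 20 higher and 2 lower (median 0.40, adjusted p = 3.8e-03, or adjusted p = 8.4e-02 with an estimated correlation), with the proton pump gene Atp4a at 2.21 ± 0.14, Chga at 2.41 ± 0.13 and Chia1 at 1.61 ± 0.08. Pancreatic acinar genes had 7 of 9 higher and 1 lower (median 0.82, or 1.41 with the deposited quantile-normalized signals, adjusted p = 1.3e-02, or adjusted p = 2.7e-01 with an estimated correlation), such as Amy2 (at least 3.21-fold). Both counts were the same adjusted over the list alone. The lists that passed against the mean of BE and BA did not pass against BE. Stem and progenitor genes had 9 of 18 higher and 2 lower (adjusted p = 1.3e-01). Matrix remodelling genes had 7 of 16 higher and 1 lower (adjusted p = 1.4e-01), and bile acid handling genes 3 of 9 lower and 0 higher (adjusted p = 1.4e-01). Krt5 (1.09 ± 0.12) and Cxcr4 (0.92 ± 0.19) were higher, Il1b was detected on 0 BE arrays and has no bound, Krt8 was lower (-0.56 ± 0.11, but 0.13 with median scaling), and Tff2 (0.56 ± 0.21) and Dclk1 (0.15 ± 0.12) did not pass, though both were past the test with median scaling (0.95 and 0.41) and with array weights (0.62 and 0.41), and Tff2 under several other settings too, such as 0.69 without BE replicate 1. With median scaling 93.7% of the called genes were higher.

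Against BA, 4046 genes changed (2258 higher, 1788 lower, 336 and 209 at least 2-fold), and 63.1% of genes had groups without overlap, where chance gives 10%. The B-lymphocyte genes Pou2af1 (-3.45 ± 0.11, adjusted p = 7.9e-09) and Tnfrsf13c (at least 7.84-fold, adjusted p = 7.4e-09) were lower in TU, in a lymphocyte list that did not pass, with 1 of 12 higher and 4 lower (median -0.02, adjusted p = 4.2e-01). Also lower were Hmga1 (-2.58 ± 0.09) and Pnliprp1 (-2.25 ± 0.16). The water channel gene Aqp1 was higher by 3.22 ± 0.13 (adjusted p = 2.9e-08), Serpinb12 at least 4.76-fold, Acot1 at least 4.50-fold and Wfdc18 at least 4.46-fold. For Acot1 the other probe, detected on all 12 arrays, gave -0.01. Stem and progenitor genes had 8 of 18 higher and 2 lower, 9 and 2 adjusted over the list alone (median 0.40, adjusted p = 3.2e-02, or adjusted p = 2.1e-01 with an estimated correlation), with Cd44 at 1.59 ± 0.08, Ephb2 at 1.12 ± 0.13 and Dclk1 lower at -0.53 ± 0.12 (not past the test at -0.18 with median scaling). Matrix remodelling genes had 8 of 16 higher and 0 lower (median 0.33, adjusted p = 4.3e-02, or adjusted p = 2.2e-01 with an estimated correlation), with Ccn2 at 0.89 ± 0.12 and the tenascin gene Tnc at 0.72 ± 0.15 (not past the test at 0.23 as the mean of its probes). Myeloid genes had 9 of 20 lower and 3 higher (median -0.56, adjusted p = 4.3e-02, or adjusted p = 3.2e-01 with an estimated correlation), among them Lyz2 (-1.23 ± 0.11), the mast cell gene Cpa3 (-1.38 ± 0.17) and the macrophage gene Cd163 (-1.10 ± 0.11), and these counts were the same adjusted over the list alone. The deposited quantile-normalized signals gave medians of 1.17 for the stem and progenitor, 0.70 for the matrix remodelling and -1.06 for the myeloid list. The bile acid handling list did not pass, with 4 of 9 lower and 0 higher, 5 and 0 adjusted over the list alone (adjusted p = 6.3e-02). Lor (2.01 ± 0.12), Krt10 (1.95 ± 0.12), Krt5 (1.16 ± 0.12) and Tff2 (1.01 ± 0.21) were higher, Il1b was detected on 0 BA arrays and has no bound, and Krt8 (-0.01 ± 0.11, but past the test at 0.62 with median scaling), Muc5ac (0.12 ± 0.28) and Cxcr4 (0.44 ± 0.19, but past the test at 0.63 without BA replicate 2) did not pass. With median scaling 90.7% of the called genes were higher. Without TU replicate 1 the count was 2661, and in a fit of the BA and TU arrays alone it was 6076.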

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

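All tests of explanations and the counts of other splits in this part were chosen only after the results they concern had been seen.

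Some genes rose against SQ in one lesion group and fell in another, both past the threshold. The direct difference between the 2 lesion groups then passed in each case, which follows from the same fit and adds no separate evidence. There were 200 such genes between BE and BA, 175 between BE and TU and 106 between BA and TU, and this difference in direction between groups is what drew attention to them. The first pair shares a chip, and the others lie on different chips.

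Muscle genes were lower in the lesion groups than in SQ, with a median of -2.02 for smooth muscle (SD over genes 0.75, 14 of 14 lower), against -0.30 for fibroblast (SD 0.53) and -0.13 for endothelial genes (SD 0.43). A lower share of epithelium in the SQ captures would raise fibroblast and muscle transcripts alike only if both tissues came with it. The smooth muscle mean lay below the fibroblast mean (difference -1.72). Its SE over genes, 0.23, treats the genes of a list as independent and does not measure the spread between captures. The difference argues against such a mixture, but not against a lower share of epithelium through muscle alone. The chip is excluded as the whole cause, because TU and SQ shared one and the smooth muscle median between them was still -1.99, with 14 members lower. For the skeletal part, striated muscle caught in unequal amounts by the SQ captures may contribute, since 9 skeletal muscle genes were higher by 0.89 on SQ replicate 1 than on the other SQ arrays. Of 1000 random lists of like brightness 0 reached this. The random lists drew genes independently, while skeletal muscle genes were correlated (estimate 0.355). A low number was therefore likely in advance and adds no support. Smooth muscle caught with the squamous epithelium, or a difference between the tissues themselves or between the genotypes, was not tested and stays open.

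Some squamous and cornified genes were higher in TU than in BE and BA (Krt5 by 1.13 ± 0.10, Lor by 1.63 ± 0.10, Krt10 by 1.21 ± 0.10), though the squamous list as a whole did not pass. Squamous epithelium like that of the SQ arrays within the TU captures is argued against as the whole cause, since the change of Krt5 would need a share of 40.3% and of the 10 brightest squamous genes that were lower in both metaplasias than in SQ, 7 stayed below the level this share needs by more than 2 SE. Among them were Krt13 (0.24 ± 0.17, needed 1.94) and Lgals7 (-1.20 ± 0.07, needed 0.87), while Krtdap, Krt10 and Lor reached theirs (Krt13 and Krtdap are named for their brightness, after their values were seen), and with median scaling, tried after this result was seen, Krt13 was at 0.93 (needed 2.95), the share was 93.8% and 6 of the same 10 stayed below. The chip cannot be told apart from the lesion type here, since TU lay on a different chip from BE and BA. The contrast of the groups by chip called 6023 genes, against 5671 and 5277 for the other pairings of the 4 groups. These counts also depend on how alike the tissues are, so they cannot decide it. Squamous differentiation within the tumors, or a difference with age or bile acid treatment, was not tested and stays open.

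The B-lymphocyte genes Pou2af1 (by 3.37 ± 0.11), Tnfrsf13c (by 3.00 ± 0.09) and Igk-C (by 2.50 ± 0.14) were higher in BA than in BE, within a chip, while the lymphocyte list did not pass (3 of 12 higher, median 0.03, adjusted p = 5.6e-01). Columnar genes were lower in 11 of 25 and myeloid genes higher in 7 of 20, which goes with a lower share of epithelium in the BA captures. Squamous (16 of 41 lower, 4 higher) and gastric mucous genes (6 of 21 lower, 3 higher) went the same way. Parietal and chief cell (11 of 20 higher, 4 lower), pancreatic acinar (7 of 9 higher, 2 lower) and intestinal genes (4 of 15 higher, 2 lower) went the other way. These lists therefore do not decide it. The mean of 36 fibroblast and smooth muscle genes changed by -0.15 (SE over genes 0.11, which treats them as independent), with 5 higher and 12 lower. This argues against a share lost to fibroblasts and smooth muscle, but cannot speak to a share lost to immune cells. The high background of BE replicate 2 and BA replicate 1 is argued against too, since without these arrays the smallest rise of the 3 genes was 2.33 and all 3 were still called. A larger number of B lymphocytes in or beside the BA captures, which would itself lower the share of epithelium, was not tested and stays open, and the labels leave open which group was given bile acid.

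Other splits of the arrays were counted in fits of the groups compared. They concern chance in the grouping of these arrays and not of animals, whose number is unknown, and the labels leave open whether arrays of a group are parts of 1 pool. For the lesions against SQ, of 100 of the 220 possible splits 1 gave as many genes (the real one, with 4584, and at most 711 for the others). For TU against metaplasia 2 of 84 splits did, since the split of the BE arrays against BA and TU gave more genes (1851) than the real one (1794). The median of the other splits was 0 genes in both comparisons, because splits that mix the groups part arrays that resemble each other. A low share was therefore likely in advance and does not exclude chance. The other 6 comparisons have 10 splits each, of which 1, the real one, was as large, too few for a share under 0.05. The real count and the highest other were 4731 and 0 for BE against SQ, 6620 and 0 for BA against SQ, 7037 and 0 for TU against SQ, 2431 and 0 for BA against BE, 3199 and 0 for TU against BE and 6076 and 0 for TU against BA.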

How the results depend on the processing

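The alternatives were planned, except that the arrays with the highest background, BE replicate 2 and BA replicate 1, were left out together as a choice made after seeing the data.

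Under the alternatives 153 counts of genes stayed within 1.5 times the main count and 17 moved by more. Of the 153, 2 came from the chip block, which could not change them. With a detection p under 0.05 on all 12 arrays 3158 genes were tested, and the counts fell with that number, to 2326 for the lesions against SQ, 2169, 2273 and 2209 for BE, BA and TU against SQ, 1617 for BA against BE, 1608 for TU against metaplasia, 1628 for TU against BE and 1554 for TU against BA, and the genes shared by the 3 comparisons against SQ to 888 higher and 591 lower. The share of called genes that were higher was then 59.2% in BE and 60.5% in BA against SQ (median of all genes higher by 0.14 in BA), and 41.5% for TU against metaplasia, 45.7% against BE and 41.6% against BA. Array weights gave 7582 genes for BA against BE, 7494 for TU against metaplasia, 7915 for TU against BE and 7076 for TU against BA, in a fit of the weights that stopped before convergence. Median scaling gave 2022 for BA against BE, a fit of the BA and TU arrays alone 6076, and the deposited quantile-normalized signals 1285 shared lower genes. For these the cause was not tested.

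Each array was left out in turn, which left its group with 2 arrays and the pooled spread. The counts then ranged from 5873 to 7500 for the lesions against SQ, 5327 to 6678 for BE, 5636 to 5943 for BA and 5420 to 5772 for TU against SQ, 2926 to 4234 for TU against BE, and 1401 to 1901 shared higher and 1824 to 2131 shared lower genes. For BA against BE they ranged from 2870 to 5620, the latter without BE replicate 2, for TU against metaplasia from 2587 to 4773, and for TU against BA from 2661 to 3318, the lowest of both without TU replicate 1. Without BE replicate 2 and BA replicate 1 together the counts were 7671 for the lesions, 6928 for BE and 6916 for BA against SQ, 5030 for BA against BE, 4769 for TU against metaplasia, 4586 against BE and 5078 against BA.

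Median scaling moved the median of all genes by 0.15 for the lesions against SQ, 0.42 for TU against SQ, 0.39 for TU against metaplasia, 0.38 against BE and 0.37 against BA. The share of called genes that were higher became 72.6%, 86.5%, 94.3%, 93.7% and 90.7% there, and 60.9% for BA against SQ. The quantile-normalized signals moved the median by 0.12 for BA against SQ. Of the values of single named genes 4949 were the same (64 of them from the chip block, which could not change them), 33 stronger, 50 weaker, 17 changed sign with the test passed neither there nor in the chosen setting, and 8 changed sign with it passed in either or both. With median scaling the 8 included Dclk1 in TU against SQ (0.29), Sox9 (0.28) and Krt8 (0.38) in TU against metaplasia, and Krt8 against BE (0.13) and BA (0.62), in comparisons where this scaling moves the median of all genes upward. Sox9 in TU against metaplasia became 0.01 as the mean of its probes, and with detection on all 12 arrays, which leaves another probe of the gene, Cdk2 became 0.21 in BA against BE and Acot1 became -0.01 in TU against BA. The deposited quantile-normalized signals, which carry no offset, ended the calls of Tff2 (0.79) and Krt8 (-0.30) in TU against metaplasia, of Dclk1 in BA against SQ (0.88) and of Muc5ac in TU against BE (-3.43), among others. With a gene's probes averaged, 48 genes were called in the opposite direction in the lesion comparison.

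Fry, which asks only whether a list moves, called 23, 22, 24 and 21 lists for the lesions, BE, BA and TU against SQ (12, 9, 10 and 11 with camera), 19 for BA against BE (7), 15 for TU against metaplasia (3), 13 against BE (2) and 16 against BA (3). With an estimated correlation 0 lists passed for BA against BE, TU against metaplasia, TU against BE and TU against BA. Of single list results under the estimated correlation and the replicate block 385 were the same, 1 was stronger, 30 weaker and 0 reversed. Most of the 385 had passed in neither fit, and the estimated correlation alone ended 28 list results that had passed. Other scalings are not part of this count.

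With the replicate number as a replicate block the lesion comparison called 6420 genes, 1 list passed for TU against BA in place of 3, and the calls of Sox9 (-0.23, adjusted p = 5.9e-02) and Krt8 (-0.29, adjusted p = 7.3e-02) in TU against metaplasia were lost. The numbers did not pair the arrays: after the group means were removed, 6 of 18 pairs of the same number correlated over 0.1 (range -0.64 to 0.62), and 3 of 12 arrays correlated best with an array of their own number. A chip block could be fitted for TU against SQ and BA against BE, each within a chip, and not for the other 6 comparisons. There it is the main fit written in another form, so its 6133 and 3622 genes equal the main counts by construction and test nothing. The series matrix holds the values of the quantile-normalized report (0 differ) and was not run separately. Signal over background limits the dim genes, whose folds the offset shrinks, and a gene seen on too few arrays, such as Cdx2 or Lgr5, was not tested rather than absent.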

Other observations

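The values in this part were chosen after the results had been seen, except that the gene lists and the rule for naming their members were fixed, and no explanation was tested for them.

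Pathway lists that did not pass as a whole still held called genes. Between BA and BE, the bone morphogenetic protein gene Bmp4 was higher by 1.39 ± 0.09 (adjusted p = 7.6e-07) and its receptor gene Bmpr2 lower (-1.70 ± 0.09, adjusted p = 1.5e-07), in a hedgehog and BMP list with 2 of 19 higher and 6 lower, 2 and 7 adjusted over the list alone (adjusted p = 3.8e-01). Of 21 p53 targets 1 rose and 3 fell (adjusted p = 6.7e-01), among them the cell cycle inhibitor gene Cdkn1a (-1.44 ± 0.11, adjusted p = 2.3e-06). Proliferation genes split, 4 of 28 higher and 6 lower (adjusted p = 9.3e-01), with the replication helicase genes Mcm4 (1.79 ± 0.09) and Mcm5 (0.81 ± 0.11) higher in BA and the mitotic kinase gene Plk1 lower (-0.53 ± 0.13, but not past the test at -0.47 with median scaling). Of 38 oxidative stress genes 3 rose and 10 fell, 5 and 12 adjusted over the list alone (adjusted p = 1.1e-01), with Aldh3a1 at 2.05 ± 0.22, G6pdx, of the pentose phosphate pathway, at -1.56 ± 0.11 and Gsta2 at -1.03 ± 0.10. The endothelial phosphatase gene Ptprb was higher by 1.82 ± 0.12, the only one of 7 endothelial genes that passed.

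Between TU and metaplasia, fibroblast genes were 5 of 22 higher and 5 lower (adjusted p = 8.5e-01). The secreted factor gene Fstl1 was at least 1.77-fold higher and Mgp higher by 1.12 ± 0.11, while the collagen genes Col5a1 (-0.90 ± 0.10, but not past the test at -0.25 with median scaling) and Col6a2 (-1.09 ± 0.23) were lower. Of 19 hedgehog and BMP genes 4 rose and 5 fell, 4 and 6 adjusted over the list alone (adjusted p = 3.1e-01), with Grem1, a BMP antagonist, at 1.24 ± 0.15 and Id2 at 0.85 ± 0.08. Among 38 oxidative stress genes 10 rose and 11 fell, 11 and 14 adjusted over the list alone (adjusted p = 5.3e-01), with the glutathione peroxidase gene Gpx2 at 1.27 ± 0.12 and the glutathione transferase genes Gsta2 at -1.22 ± 0.08 and Gstm1 at -0.94 ± 0.08 (not past the test at -0.26 with median scaling). Of 9 pancreatic acinar genes 6 rose and 2 fell (adjusted p = 1.7e-01), Amy2a5 by 1.32 ± 0.08 and Amy2 by 1.57 ± 0.17, with Rnase1 lower at -1.33 ± 0.16. The counts of the other lists here were the same adjusted over the list alone.

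Single genes of gastric and pancreatic enzymes, chosen after their values were seen, were bright on the SQ arrays, while Pga5 and Cela1 were detected on 0 of them. The mean log2 intensity in SQ was 11.61 for Pgc, 10.29 for Chia1 and 10.25 for Clps, with the 3 SQ arrays detecting each. In Il1b the mean was 4.88 on TU, where 3 of 3 arrays detected it, and 4.56 on SQ, 4.57 on BE and 4.48 on BA, where 0 arrays did. The lowest detected log2 value was 4.59 to 4.81 on TU, 4.86 to 4.97 on SQ, 4.78 to 5.33 on BE and 4.97 to 5.21 on BA. A value of 4.88 would thus go undetected on most of the other arrays, and detection on TU alone is not read as a difference in Il1b.

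For bright probes, the variance of the difference between 2 arrays was compared with the variance of their beads. The ratio was 1.32 to 9.82 for the 12 pairs within a group (median 1.67) and 11.35 to 79.76 for the 54 pairs across groups (median 29.84). Within SQ it was 1.70 for replicates 2 and 3, and 5.20 and 9.82 for the pairs with replicate 1. Within BE it ranged from 1.59 to 3.86, within BA from 1.32 to 1.81 and within TU from 1.46 to 1.64.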
